A study of Homo sapiens with 9 samples.

How the data were processed

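RNA was measured in 9 samples of MCF10A, an established human mammary epithelial line that does not form tumors. The cells carried an empty vector or a constitutively active HER2, the receptor encoded by ERBB2. They received a control siRNA or siRNA against YAP1 and WWTR1, the genes of the transcriptional co-activators YAP and TAZ. Reagents numbered 1 and 3 were used in each line, and they are called siRNA 1 and siRNA 3. Cells were replated 24 h after transfection onto plastic or onto a polyacrylamide hydrogel of 0.5 kPa and were harvested 24 h later. Per the labels, the libraries were made from total RNA after ribosomal RNA depletion.

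The deposited matrix held raw counts per gene symbol, with no normalization by the authors. The processing notes named STAR 2.5.3a, featureCounts and edgeR and the genome build hg19. Strand, annotation and the treatment of multiply mapping reads were not given in the sources used here. Genes are identified by symbol alone, since the matrix gave no other identifier. Of 25370 entries, 25369 had a symbol, and the entry without a symbol had 0 counts. At least 1 count was present for 19300 genes, and 0 columns belonged to samples outside the study. The totals ran from 24425556 counts in the HER2 control library on plastic to 78945981 in the empty-vector library with siRNA 3. A floor of 3 counts corresponded to 0.0371 to 0.131 in library-scaled counts (CPM), depending on the library.

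Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group with a minimum count of 10, which left 16117 genes, and libraries were scaled by TMM. The group-means model took the 6 groups as they stand. It gave 3 residual degrees of freedom, 1 between the empty-vector control libraries A and B and 1 between siRNA 1 and siRNA 3 in each line. The quasi-likelihood F test was used, and p-values were adjusted by Benjamini-Hochberg at 0.05. A group with 1 library was assumed to vary like the other groups. The common biological coefficient of variation was 0.408. An alternative fixed in advance, called the reagent model here, added 1 term for siRNA 3 against siRNA 1, shared by both lines. It had 2 residual degrees of freedom and a coefficient of variation of 0.209.

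The labels give the same siRNA numbers in each line, which was read as pairing by reagent. That is a judgment, since a number names a reagent and not a batch or a day, and there are only 2 pairs. The difference between siRNA 3 and siRNA 1 in empty-vector cells correlated with that in HER2 cells at r = 0.42 across 16117 genes and at r = 0.67 across the most abundant 4030 genes. This correlation was computed after the counts of both models had been seen. Calls of the reagent model refer to the mean of these 2 reagents, so a gene moved by 1 reagent alone can pass. Its spread rests on the A and B pair and on how far the reagent difference varied between lines. Counts without control A or B are therefore given beside it.

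Groups, comparisons, tests, alternatives, 24 gene lists, 4 lists of cell type markers and the rule for named genes were set before the data were examined. The rule took, in each direction, the 12 genes with the largest fold change among genes past the threshold, with a mean log2 CPM of at least 2. Every library of 1 group had to lie on the same side of every library of the other. Symbols of uncharacterised loci and of small RNA classes were left out. Some genes that met the rule are not reported here. For the interactions and for siRNA 3 against siRNA 1 the number was 5. The group-means model gave 0 calls in most comparisons, so the rule was also applied to the reagent model, a step added after the data were seen. Members of lists named as examples were chosen after their values were seen.

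Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2. The correlation between genes was preset at 0.01, and p-values were adjusted over the 24 lists. The tests were repeated with a correlation estimated from the residuals, which removed every camera call of the group-means model, and with fry. A list p quoted without a qualifier is from camera with the preset correlation in the group-means model, except for siRNA 3 against siRNA 1, where it is from the reagent model. Members that passed are counted in the reagent model, over all genes tested and adjusted over the list alone. The 24 lists were YAP/TAZ targets from a published signature, SRF and actin cytoskeleton, integrins and focal adhesion, extracellular matrix, DNA replication, mitosis, basal and luminal mammary epithelium, mesenchymal genes, cornified envelope, ERK output and ERBB ligands, sterol synthesis, fatty acid synthesis, glycolysis and hypoxia, interferon response, NF-kB and cytokines, ATF4 and unfolded protein response, p53 targets, TGF-beta and SMAD targets, Notch and Wnt, replication-dependent histones, oxidative phosphorylation, ribosomal proteins, and lysosome and autophagy.

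Genes with 0 counts in a group are given as a bound against 3 counts over the group, and genes with 1 to 3 counts as a ratio with its 95% counting interval. The bound takes the counts of the other group as exact. Neither was computed for averages over both lines or for siRNA 3 against siRNA 1. Intervals and floors cover counting error only. The replicates were not stated to be separate cultures, so p-values measure only the spread between these samples, which may be technical. Transcript lengths came from GENCODE release 29, on another build than hg19, and were used for lengths alone.

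Both models were tested on simulated data with 67, 67 and 66 genes changed by 1, 2 and 3 on the log2 scale. For HER2 against empty vector on plastic, the group-means model recovered 1.5%, 31.3% and 74.2% of them, with 5 false among 76 calls. For soft hydrogel in empty-vector cells, the reagent model recovered 26.9%, 92.5% and 100%, with 11 false among 169 calls. For siRNA in both lines it recovered 92.5%, 100% and 100%, with 17 false among 243 calls. Counts were drawn with the dispersion of the model under test. For the reagent model each gene had the same simulated reagent difference in both lines, so its assumption held by construction. These rates therefore do not test that assumption and may be better than those in the real data. With a log2 change of 1 in every mitosis gene the camera test gave adjusted p = 8.41e-15, 1.21e-47 and 3.98e-69 in these settings. With an estimated correlation the same lists had adjusted p = 0.0767, 0.0800 and 0.0549. Of the 23 other lists, 1, 0 and 1 passed with the preset correlation. Genes were drawn independently of each other, so these list values do not show how the preset correlation fares where members vary together.

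The alternatives were RLE and upper quartile scaling, no filter and a filter at 50 counts, a robust fit, an additive model, DESeq2 1.42.0, only the groups compared, and each library of a pair left out in turn. Fits with libraries of 1 siRNA only, and list tests with 1 siRNA or without each library of a pair, were added after the data were seen. So were simulated correlations for single reagents and divisions of the plastic libraries with reagent as a term. With upper quartile scaling the median log2 fold change of all genes was 0.17 for siRNA in empty-vector cells and in both lines, 0.12 for siRNA in HER2 cells and -0.11 for HER2 on plastic. With TMM these medians were 0.07, 0.10, 0.07 and -0.08.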

Results

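Gene expression was measured by RNA-seq in 9 libraries of MCF10A cells that differed in oncogene, support and siRNA. Empty-vector cells on plastic gave 2 libraries with control siRNA (A and B) and 2 with YAP/TAZ siRNA (1 and 3). HER2 cells on plastic gave 1 control library and 2 with YAP/TAZ siRNA (1 and 3). Each line gave 1 control library on the soft hydrogel of 0.5 kPa, a support far more compliant than plastic. Total counts were 68646362 and 74344596 in the empty-vector controls A and B, 50073588 with siRNA 1 and 78945981 with siRNA 3 in empty-vector cells, and 47978557 on the soft hydrogel. In HER2 cells they were 24425556 in the control, 67857398 with siRNA 1, 59133388 with siRNA 3 and 71058119 on the hydrogel. Across genes, log2 CPM of controls A and B correlated at r = 0.994, and libraries with siRNA 1 and siRNA 3 at r = 0.950 in empty-vector and r = 0.952 in HER2 cells. The first principal component held 51.1% of the variance and placed the 4 HER2 libraries between 68.5 and 119.6 and the 5 empty-vector libraries between -121 and -36.5. The third component held 13.4%. It placed the siRNA 1 and hydrogel libraries of both lines between -66.5 and -35.5, and the control and siRNA 3 libraries on plastic between 21.6 and 52.3. In what follows, log2 fold changes carry their standard error after ±.

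ERBB2, the oncogene introduced, stood at 59.1 ± 2.01 CPM (SD, n = 2) in empty-vector controls and at 614 CPM in the HER2 control. It was 416 CPM in HER2 cells on the hydrogel and 401 ± 56.8 CPM (SD, n = 2) in HER2 cells with YAP/TAZ siRNA. The log2 fold change of ERBB2 between lines was 3.38 ± 0.26 on plastic (edgeR adjusted p = 0.0166), 2.51 ± 0.32 on the hydrogel (adjusted p = 0.0359) and 2.25 ± 0.23 under siRNA (adjusted p = 0.013). YAP1 transcripts fell from 84.5 ± 0.84 to 14.3 ± 0.0171 CPM (SD, n = 2 each) with siRNA in empty-vector cells, and 16.9% were left with either reagent. In HER2 cells YAP1 stood at 115 CPM in the control, with 8.5% left after siRNA 1 and 16.5% after siRNA 3. WWTR1, which encodes TAZ, was left at 18.2% and 28% in empty-vector cells and at 17.1% and 28.4% in HER2 cells, after siRNA 1 and siRNA 3 in that order. Over both lines the log2 fold change was -2.81 ± 0.19 for YAP1 (adjusted p = 0.00395) and -2.17 ± 0.08 for WWTR1 (adjusted p = 0.00329) in the reagent model, and adjusted p = 0.0557 for each gene in the group-means model. On the hydrogel YAP1 stood at 81.6 CPM in empty-vector and 71.2 CPM in HER2 cells, and WWTR1 at 66.0 and 146 CPM.

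**Figure D1:**
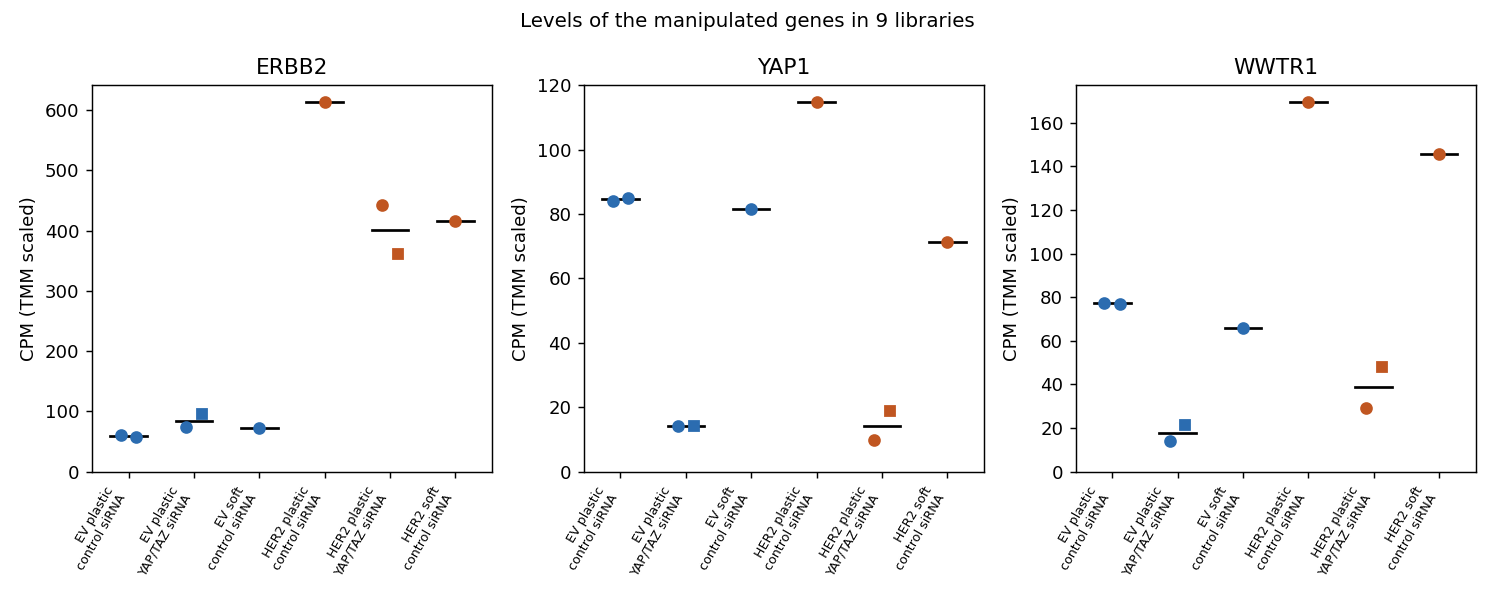
Levels of ERBB2, YAP1 and WWTR1 in each of the 9 libraries, as CPM after TMM scaling, by group; circles are libraries, squares are siRNA 3 libraries and black lines are group means. ERBB2 was 361.3 CPM or more in the 4 HER2 libraries and 95.5 CPM or less in the 5 empty-vector libraries, and YAP1 was 18.9 CPM or less in the 4 libraries with YAP/TAZ siRNA.

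The comparison of HER2 with empty-vector controls on plastic asked what the activated receptor changes on a stiff support. Epithelial genes were among those lowered. CDH1, the adherens junction cadherin of epithelia, was 444 ± 1.97 CPM (SD, n = 2) in empty-vector and 1.18 CPM in HER2 controls. KRT14, a basal keratin, was 193 ± 2.65 and 0.875 CPM, and TP63, a regulator of basal epithelial identity, was 79.1 ± 0.774 and 0.438 CPM. TP63 passed the group-means model in edgeR (adjusted p = 0.0118), while CDH1 and KRT14 did not (adjusted p = 0.0796 and 0.146) and passed the reagent model (adjusted p = 0.00223 and 0.00254). Among the genes named by the rule, SERPINB2 fell by 9.5 ± 0.46 (adjusted p = 0.0118), and KRT17 changed by -8.10 ± 0.79 and the epithelial splicing factor ESRP1 by -7.81 ± 0.82. CST6 had 0 counts in the HER2 control and was at least 65.2-fold lower, and CCDC64 at least 50.3-fold lower. Also named were FEZ1, PNLIPRP3, TMEM40, MARVELD3, RNASE7 and PTAFR, whose ratios from 1 to 3 counts ran from 187 (counting interval 63.8 to 905) for PTAFR to 385 (69.1 to 15200) for FEZ1. Higher in HER2 cells were ST6GALNAC3 (6.17 ± 0.38, adjusted p = 0.0118), KIAA1644 (5.62 ± 0.70), C10orf90, TBL1X, STK32A (4.35 ± 0.28), KCNQ3, SRGN (3.81 ± 0.31), FRMD3 and CCDC102B. PPARG, the regulator of adipocyte differentiation, was 145 CPM against 7.09 CPM (4.35 ± 0.54, adjusted p = 0.0407), and ZEB2, a repressor of epithelial genes, rose by 3.50 ± 0.50 (adjusted p = 0.0497).

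By the group-means model in edgeR, 166 of 16117 genes differed, 37 higher and 129 lower in HER2 cells. The reagent model called 3598, 1464 higher and 2134 lower, and DESeq2 2306. All 166 genes kept their sign in every alternative and were among the calls of the reagent model and of DESeq2. Without control A or without control B, 0 genes passed the group-means model, against 3353 at an unadjusted p under 0.05 with all libraries. Without HER2 siRNA 1 or siRNA 3 the counts were 1011 and 1004, and the reagent model called 502 without control A and 617 without control B. Without any 1 of the 4 siRNA libraries, where the spread rests on the A and B pair, it called 9510 to 9606.

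Epithelial lists were lower in HER2 cells too, with members counted in the reagent model. Of 20 basal mammary genes, 14 fell (15 adjusted over the list alone) and 0 rose, the median being -3.19 (adjusted p = 4.64e-08). Of 33 cornified envelope genes, which build the squamous barrier, 19 fell (20 over the list alone), with a median of -6.27 (adjusted p = 2.42e-05), or -2.70 with genes at 0 counts at their bound. Of 25 luminal genes 11 fell and 1 rose (11 and 1 over the list alone; median -1.56, or -1.16 at the bounds; adjusted p = 0.00196), with ALDH1A3 down by 5.52 ± 0.73. Extracellular matrix genes had a median of -1.05 (-1.01 at the bounds; adjusted p = 0.0043). There, 10 of 31 fell (12 over the list alone), such as the hemidesmosome partners LAMA3 (-6.34 ± 0.30) and COL17A1 (-5.51 ± 0.36), and 3 rose, among them SERPINE2 (2.39 ± 0.19). Actin cytoskeleton genes were lower (median -0.72, adjusted p = 0.00233; 10 of 25 fell, 10 over the list alone), and so were YAP/TAZ targets (median -0.59, adjusted p = 0.043, but 0.0765 without empty-vector siRNA 1 and 0.0793 without siRNA 3; 9 of 22 fell and 1 rose, 9 and 1 over the list alone), with CTGF at -1.01 ± 0.19 and CYR61 at -1.06 ± 0.14. Of 24 mesenchymal genes 8 rose and 2 fell (8 and 2 over the list alone; median 0.40, 0.39 at the bounds; adjusted p = 0.0236), among them ZEB1 (2.06 ± 0.22) and the intermediate filament VIM (0.75 ± 0.15). All of these lists had adjusted p = 0.689 with an estimated correlation.

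Of the cell cycle lists, only that of mitosis passed in this comparison. Mitosis genes had a median of 0.70 (adjusted p = 0.000184), though only 3 of 38 rose one by one (1 over the list alone), MKI67 by 1.83 ± 0.16. DNA replication genes (0.31, adjusted p = 0.0766) and replication-dependent histones (-0.66, adjusted p = 0.0912) did not pass. Of 26 p53 targets 9 fell and 1 rose (12 and 1 over the list alone; median -0.77, adjusted p = 0.0043), with the cell cycle inhibitor CDKN1A at -2.63 ± 0.17 and PLK2 at -3.26 ± 0.16. Of 25 Notch and Wnt genes 6 fell and 1 rose (7 and 1 over the list alone; median -0.81, -0.67 at the bounds; adjusted p = 0.0265), JAG2 by -2.55 ± 0.24. Ribosomal protein genes had a median of -0.45 (adjusted p = 0.00363), with 15 of 38 lower and 2 higher (20 and 2 over the list alone). Across genes, longer transcripts had higher fold changes in this comparison (Spearman 0.22), and ribosomal transcripts are short (median principal length 1007, against 2988 for genes tested), so length was not separated from HER2 here. Each of these 4 lists had adjusted p = 0.689 with an estimated correlation. ERK output and ERBB ligands did not pass (median 0.15, mean -0.20, adjusted p = 0.255): 8 of 32 rose, such as FOSL1 (2.23 ± 0.21) and the ligand EREG (2.48 ± 0.36), and 5 fell, such as the ligand HBEGF (-1.31 ± 0.29). Interferon genes did not pass either (median 0.17, mean -0.21, adjusted p = 0.254), nor did glycolysis (0.22, adjusted p = 0.0766), ATF4 and unfolded protein response (0.29, adjusted p = 0.265), NF-kB (-1.15, adjusted p = 0.0912) or TGF-beta genes (-0.64, adjusted p = 0.0912).

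The HER2 response was then followed on the hydrogel and under siRNA. The siRNA libraries are not independent of the choice of genes, since they gave 2 of the 3 residual degrees of freedom behind it. Without empty-vector siRNA 1 or siRNA 3, 79 and 81 of the 166 genes were still called. Of the 166 genes, 158 (95.2%) had the same sign between HER2 and empty-vector cells on the hydrogel, and 166 under YAP/TAZ siRNA. For the 37 genes higher on plastic the median log2 fold change was 3.05 on plastic, 2.20 on the hydrogel and 2.21 under siRNA. For the 129 lower genes it was -3.68, -3.77 and -3.21, and these medians stayed as they are with genes at 0 counts at their bound. The plastic medians come from the comparison that chose the genes, which alone can make them too large. A smaller median in another setting therefore does not show a weaker response to HER2. PPARG, ZEB2 and SRGN were higher in HER2 cells in all 3 settings. This is a description over genes, which are not replicates, and the hydrogel rests on 1 library per line.

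**Figure D2:**
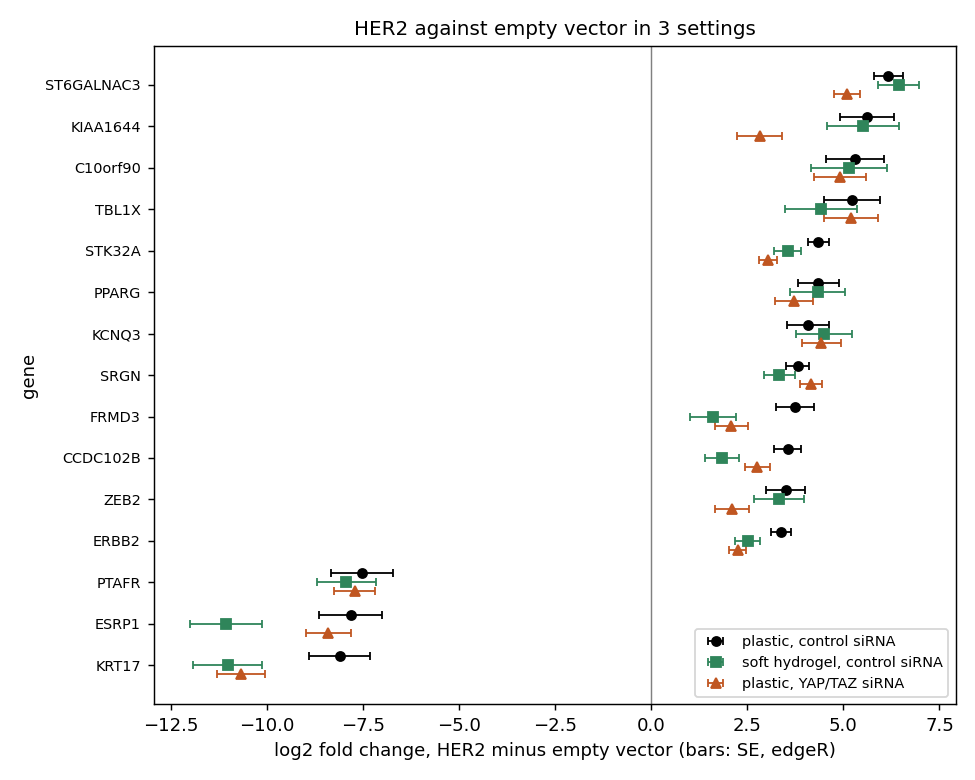
Log2 fold change of HER2 against empty vector on plastic (black circles), on the soft hydrogel (green squares) and under YAP/TAZ siRNA (orange triangles) for 15 of the 23 genes named, with bars for the standard error (edgeR); 8 genes with 3 or fewer counts in a library are not drawn. The genes drawn kept their sign in all 3 settings, with ERBB2 at 3.38, 2.51 and 2.25.

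The soft hydrogel was compared with plastic in empty-vector cells to see what loss of stiffness does without an oncogene. Targets of YAP/TAZ and matrix genes fell. The reagent model gave CTGF -2.51 ± 0.20 (adjusted p = 0.00881), CYR61 -2.29 ± 0.15 (adjusted p = 0.00662) and ANKRD1 -4.89 ± 0.80 (adjusted p = 0.0224), and THBS1, a matricellular protein, went from 4890 ± 84.6 CPM (SD, n = 2) to 229 CPM (-4.41 ± 0.24). Cell cycle genes fell with them, PLK1 by -2.99 ± 0.26 and MKI67 by -2.62 ± 0.19. Among genes that rose were S100A7 by 8.10 ± 0.16 (adjusted p = 0.000688), SPRR3 by 8.10 ± 0.28, MUC21 by 8.47 ± 0.41, LCN2 by 6.12 ± 0.37 and S100A8 from 19.7 ± 0.0821 CPM (SD, n = 2) to 1020 CPM. The rule also named S100P, VTCN1, CCL5, PSCA, CEACAM6, RARRES1 and HP among higher genes. HP had 0 counts on plastic and 6 counts (0.123 CPM) in the 1 hydrogel library. Its bound of 6.01-fold takes those 6 counts as exact, so the size of this change is uncertain. Among lower genes it named HIST1H2AB (-4.56 ± 0.44), CDH11, HIST1H3G, WDR62, PKMYT1, ESPL1, LRCH2, HIST1H3F, HIST1H2AH and CHTF18.

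All 38 mitosis genes fell on the hydrogel in empty-vector cells in the reagent model, by which members are counted here (38 adjusted over the list alone), with a median of -2.73 (list adjusted p = 1.95e-22). The list p is from the group-means model, where edgeR called 0 single genes (3064 at an unadjusted p under 0.05, 1843 by DESeq2). Of 36 DNA replication genes 27 fell (35 over the list alone; median -2.38, adjusted p = 2.23e-20), such as the helicase subunit MCM2 (-2.85 ± 0.50), and of 18 replication-dependent histones 16 fell (18 over the list alone; median -3.13, adjusted p = 1.87e-12). Of 38 interferon genes 26 rose and 1 fell (31 and 1 over the list alone; median 1.58, adjusted p = 8.46e-16), with IFI6 up by 3.55 ± 0.16 and OAS2 by 3.71 ± 0.29. This list had adjusted p = 0.172 with an estimated correlation, and adjusted p = 0.00909 by fry. Of 33 cornified envelope genes 20 rose (23 over the list alone; median 3.13, adjusted p = 1.16e-07, and adjusted p = 0.505 with an estimated correlation), IVL by 2.99 ± 0.21. Of 25 luminal genes 11 rose and 1 fell (16 and 1 over the list alone; median 2.25, 2.27 at the bounds; adjusted p = 4.54e-05, and adjusted p = 0.43 with an estimated correlation), the protease inhibitor SLPI by 3.25 ± 0.12. CDH1 rose by 1.26 ± 0.24 (adjusted p = 0.0283). The mitosis, replication and histone lists had adjusted p = 0.425 with an estimated correlation.

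Contact and contractility genes were lower on the hydrogel in these cells. Of 22 YAP/TAZ targets 11 fell and 0 rose (12 and 1 over the list alone; median -0.71, adjusted p = 0.00111). Of 24 integrin and focal adhesion genes 12 fell and 1 rose (15 and 1 over the list alone; median -0.86, adjusted p = 1.23e-05), the caveolar coat protein CAV1 by -2.36 ± 0.15. Of 31 matrix genes 14 fell and 1 rose (15 and 2 over the list alone; median -1.45, -1.29 at the bounds; adjusted p = 3.15e-05), the basement membrane chain COL4A1 by -3.08 ± 0.32. Of 25 actin cytoskeleton genes 10 fell (13 over the list alone; median -0.65, adjusted p = 0.000118), the actin crosslinker FLNA by -2.42 ± 0.13. Sterol synthesis genes fell in 10 of 23 and rose in 1 (14 and 1 over the list alone; median -0.54, adjusted p = 5.14e-06). Lysosomal genes rose in 12 of 30 (14 higher and 1 lower over the list alone; median 0.57, adjusted p = 0.000298), p53 targets in 13 of 26 (13 and 1; median 0.63, adjusted p = 0.00284), oxidative phosphorylation genes in 11 of 24 (12; median 0.45, adjusted p = 0.000447) and ribosomal proteins in 6 of 38 (4; median 0.26, adjusted p = 0.00379). The lists of this paragraph had adjusted p = 0.425 or 0.43 with an estimated correlation, and 0.816 for ribosomal proteins. Over all genes, edgeR called 0 genes in the group-means model, with 3064 at an unadjusted p under 0.05, a smallest adjusted p of 0.0502 and 1843 calls by DESeq2. With reagent as a term edgeR called 3254 (1650 higher, 1604 lower), 344 without control A and 308 without control B. It called 10260 to 10299 without an siRNA library, and without HER2 siRNA 1 or siRNA 3 the group-means model called 628 and 638.

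In HER2 cells the same change of support was seen in 1 library against 1, so its spread came from other groups, and the hydrogel library had the fewest genes at 1 to 3 counts of all 9 (294). CYR61 went from 77.7 to 9.62 CPM (-3.01 ± 0.17, adjusted p = 0.0432 in the reagent model), THBS1 from 1070 to 140 CPM (-2.93 ± 0.24, adjusted p = 0.0447) and POSTN, a matricellular protein, from 92 to 4.11 CPM (-4.48 ± 0.25, adjusted p = 0.0432). Lower as well were COL17A1 (-4.26 ± 0.37), ITGB6, an integrin that activates TGF-beta (-2.5 ± 0.17), and the cytokine IL1A (-1.87 ± 0.16). ID3, an inhibitor of basic helix-loop-helix factors, rose by 3.69 ± 0.28 and the aldo-keto reductase AKR1C1 by 2.44 ± 0.16. Higher genes named were also SCNN1B, SNCG, SULT1E1 and ASS1, and lower ones TRIML2, SFTA1P, NAV3, HNRNPH3, VCAN and NSRP1, with DAPP1 at 0 counts and at least 18.5-fold lower. The bound for DAPP1 covers counting error only. It does not allow for a loss of rare transcripts in the hydrogel library, which was not tested. CTGF at -1.70 ± 0.21 and MKI67 at -1.67 ± 0.19 did not pass (adjusted p = 0.0522 each).

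YAP/TAZ targets were lower as a list on the hydrogel in HER2 cells (median -1.13, adjusted p = 1.53e-06, and adjusted p = 0.578 with an estimated correlation). Of 22 members 1 fell over all genes, and 14 fell and 1 rose adjusted over the list alone. Oxidative phosphorylation genes were higher, with a median of 0.81 (adjusted p = 5.74e-12, and adjusted p = 0.607 with an estimated correlation), 0 of 24 passing over all genes and 19 over the list alone, such as COX7C at 1.14 ± 0.16. Ribosomal proteins had a median of 0.60 (adjusted p = 2.43e-10), with 0 of 38 passing over all genes and 31 over the list alone. Histones had a median of 1.06 (adjusted p = 0.000212), lysosomal genes of 0.32 (0.38 at the bounds; adjusted p = 0.0316) and interferon genes of 0.36 (adjusted p = 0.0396). In these 3 lists 0 members passed over all genes, and 0, 5 and 2 were higher over the list alone. Matrix genes had a median of -0.62 (-0.61 at the bounds; adjusted p = 0.00098), with 2 of 31 lower (8 over the list alone), and basal genes of -0.43 (-0.38 at the bounds; adjusted p = 0.0408), with 1 of 20 lower (4 over the list alone). Mitosis genes had a median of -0.37 (adjusted p = 0.0408) and sterol genes of -0.15 (adjusted p = 0.0396), with 0 lower over all genes and 1 and 4 over the list alone. Mitosis genes no longer passed without empty-vector siRNA 1 or siRNA 3 (adjusted p = 0.139 and 0.147), nor did basal genes (0.0883 and 0.0849) or interferon genes (0.0522 and 0.0562) without HER2 siRNA 1 or siRNA 3, nor sterol genes with libraries of siRNA 1 only (0.0764) or siRNA 3 only (0.0782). The lists other than YAP/TAZ targets and oxidative phosphorylation had adjusted p = 0.903 with an estimated correlation. DNA replication genes had a median of 0.08 (adjusted p = 0.938). The group-means model in edgeR called 0 genes, with 1568 at an unadjusted p under 0.05 and 303 by DESeq2. By the reagent model, the count was 30 (6 higher, 24 lower), 0 without control A or without control B, 251 with no filter on low counts and 1874 with DESeq2. It called 7844 to 7910 without an siRNA library. Across genes, longer transcripts had lower fold changes in this comparison (Spearman -0.37 over 10666 genes), against 0.01 in empty-vector cells.

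Averaged over both lines, the hydrogel lowered THBS1 by -3.67 ± 0.17 (adjusted p = 0.00517), POSTN by -3.75 ± 0.17 and CYR61 by -2.65 ± 0.11, and raised the calcium-binding S100P by 5.4 ± 0.29 and the sodium channel subunit SCNN1B by 4.12 ± 0.15. Of 22 YAP/TAZ targets 12 fell and 1 rose (14 and 1 over the list alone; median -0.93, adjusted p = 6.72e-07, and adjusted p = 0.285 with an estimated correlation). Of 38 interferon genes 17 rose (29 higher and 1 lower over the list alone; median 0.93, adjusted p = 4.06e-13, and adjusted p = 0.226 with an estimated correlation and 0.0276 by fry). Oxidative phosphorylation genes rose in 15 of 24 (17 over the list alone; median 0.60, adjusted p = 3.84e-11, and adjusted p = 0.377 with an estimated correlation). Across genes, the averaged fold changes correlated with transcript length at -0.2 (Spearman), and the part of length in this list was not tested. Among other named genes AZGP1, MUC16, CHI3L1, ELF3, AQP3 and the fatty acid receptor CD36 (4.17 ± 0.73) rose, and ZBED2, FGF5, CDH11 and CCBE1 fell. AZGP1, MUC16 and ELF3 had 0 counts in the HER2 control on plastic, so the size of their averaged rise is uncertain. The group-means model in edgeR called 0 genes, with 2589 at an unadjusted p under 0.05 and 1291 by DESeq2. The reagent model called 2241 (1107 higher, 1134 lower) and with DESeq2 3583, 286 without control A, 262 without control B and 9123 to 9229 without an siRNA library.

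YAP/TAZ siRNA on plastic asked which genes need these co-activators. In empty-vector cells mitotic genes fell. PLK1 went from 64.8 ± 2.71 to 5.42 ± 5.17 CPM (SD, n = 2 each), a change of -4.0 ± 0.20 (adjusted p = 0.00541) and MKI67 from 254 ± 7.72 to 24.0 ± 14.5 CPM (SD, n = 2 each; -3.55 ± 0.15). CTGF (-2.92 ± 0.16), CYR61 (-2.92 ± 0.12), ANKRD1 (-3.77 ± 0.56) and AMOTL2, a partner of YAP at junctions (-2.35 ± 0.16), fell too. Named among lower genes were also PIF1 (-4.96 ± 0.37), MCM10, SPC25, TROAP, ESPL1 and HIST1H3G. Higher were the lysosomal glycoprotein GPNMB (6.64 ± 1.25, adjusted p = 0.0222), the transcription factor MAF, the collagenase MMP1 (6.07 ± 0.72, adjusted p = 0.00936), MMP10, CHRNA9, the BH3-only gene BMF, SPP1, IL33, CHI3L1, S100A7, CEACAM6 and RNF128. Some of these differed between reagents, siRNA 3 being above siRNA 1 by 7.07 ± 1.06 for IL33, 5.48 ± 0.69 for SPP1 and 4.51 ± 0.66 for MMP1, and below it by -7.55 ± 0.21 for S100A7 and -3.81 ± 0.34 for CEACAM6. In empty-vector cells S100A7 was at 224.6 CPM with siRNA 1 and 1.19 CPM with siRNA 3, against 0.84 CPM in controls. AKR1C1 rose by 3.92 ± 0.12 in this line and by 3.91 ± 0.16 in HER2 cells.

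All 38 mitosis genes fell with siRNA in empty-vector cells in the reagent model (38 adjusted over the list alone; median -3.09, adjusted p = 3.44e-28), as did 36 of 36 replication genes (median -2.47, adjusted p = 3.09e-25) and 18 of 18 histones (median -3.49, adjusted p = 1.56e-15). Of 22 YAP/TAZ targets 10 fell and 0 rose (11 over the list alone; median -0.36, adjusted p = 5.4e-05). Sterol synthesis genes fell in 12 of 23 (16 over the list alone; median -0.46, adjusted p = 7.13e-06). Lysosomal genes rose in 19 of 30 (24 higher and 2 lower over the list alone; median 0.85, adjusted p = 7.13e-06), the autophagy receptor SQSTM1 by 2.28 ± 0.22. Interferon genes rose in 14 of 38 and fell in 2 (16 and 2 over the list alone; median 0.53, adjusted p = 0.000155), and p53 targets rose in 13 of 26 and fell in 1 (17 and 2 over the list alone; median 0.69, adjusted p = 0.00234), CDKN1A by 1.30 ± 0.12. These 8 lists had adjusted p = 0.41 with an estimated correlation.

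Other lists passed as well. TGF-beta genes rose in 8 of 22 (9 over the list alone; median 1.12, adjusted p = 0.0035), matrix genes in 11 of 31 with 3 lower (14 and 4 over the list alone; median 0.67, adjusted p = 0.0356), and integrins in 9 of 24 with 2 lower (11 and 2 over the list alone; median 0.42, adjusted p = 0.0427). They had adjusted p = 0.683, 0.697 and 0.683 with an estimated correlation. FN1 rose by 1.51 ± 0.10 and its receptor subunit ITGA5 by 1.51 ± 0.10, while THBS1 fell by 3.1 ± 0.17. Mesenchymal genes rose in 9 of 24 and fell in 3 (10 and 3 over the list alone; median 0.58, adjusted p = 0.0315, and adjusted p = 0.705 with an estimated correlation). Fatty acid synthesis genes fell in 6 of 14 (8 over the list alone; median -0.33, adjusted p = 0.0155, and adjusted p = 0.683 with an estimated correlation), FASN by -1.13 ± 0.15. Cornified envelope genes rose in 15 of 33 (15 over the list alone; median 2.45, adjusted p = 0.000696, and adjusted p = 0.697 with an estimated correlation), but their median against the controls was 2.97 with siRNA 1 and -0.31 with siRNA 3. Without empty-vector siRNA 1 this list turned to the other direction and did not pass (adjusted p = 0.563). Matrix (adjusted p = 0.347), integrin (0.229), mesenchymal (0.498) and fatty acid genes (0.22) did not pass without empty-vector siRNA 3, nor did integrins without HER2 siRNA 1 or siRNA 3 (0.0622 and 0.0635). The group-means model in edgeR called 0 genes, with 3473 at an unadjusted p under 0.05 and 2274 by DESeq2, and 1431 without HER2 siRNA 1 and 1418 without HER2 siRNA 3. With reagent as a term edgeR called 4139 (1951 higher, 2188 lower), 558 without control A and 525 without control B, and 8290 to 10600 without an siRNA library.

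In HER2 cells YAP/TAZ siRNA lowered MKI67 from 903 to 207 ± 157 CPM (SD, n = 2), by -2.36 ± 0.16 (adjusted p = 0.022), CYR61 by -2.23 ± 0.13, CTGF by -1.74 ± 0.17 and PLK1 by -1.68 ± 0.21. CDKN1A rose from 20 to 111 ± 29.6 CPM (SD, n = 2), by 2.45 ± 0.16, SQSTM1 by 2.77 ± 0.29, IFI6 by 3.17 ± 0.20, FN1 by 1.84 ± 0.13 and ID3 by 2.20 ± 0.27. The rule named SYT12, TMOD1, MGP, GPRC5C, AKR1B10 and AQP3 among higher genes. AZGP1 was at least 13.9-fold and CCDC64 at least 2.2-fold higher, and BDKRB2 had a ratio of 23.5 (counting interval 7.98 to 114). Lower were YAP1 itself, MDC1 (-2.86 ± 0.19), HMGN5, ANP32B, NFIC and EIF5B, with ZNF750 at least 10.9-fold lower and SCEL at a ratio of 21.8 (4.36 to 211).

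Mitosis genes had a median of -1.21 in this line (adjusted p = 6.24e-15, and adjusted p = 0.706 with an estimated correlation), with 5 of 38 lower over all genes and 35 over the list alone. Replication genes had a median of -0.85 (adjusted p = 4.89e-09, and adjusted p = 0.779 with an estimated correlation; 2 of 36 lower, 2 over the list alone) and histones of -0.42 (adjusted p = 0.00965, and adjusted p = 0.841 with an estimated correlation; 0 of 18 lower). By library, in the HER2 control, with siRNA 1 and with siRNA 3, the medians were 0.70, 0.08 and -1.38 for mitosis, 0.31, -0.05 and -1.36 for replication, and -0.66, -0.46 and -2.30 for histones. Without HER2 siRNA 3 the histone list turned to the other direction (adjusted p = 0.287), and without empty-vector siRNA 3 it did not pass (adjusted p = 0.0516). Of 22 YAP/TAZ targets 5 fell and 1 rose (9 and 1 over the list alone; median -0.53, adjusted p = 0.000111), and of 23 sterol genes 1 fell (7 over the list alone; median -0.23, adjusted p = 0.000534), HMGCS1 by -1.04 ± 0.14. Interferon genes rose in 5 of 38 (16 higher and 1 lower over the list alone; median 0.89, adjusted p = 2.61e-08, and adjusted p = 0.441 with an estimated correlation). Lysosomal genes rose in 3 of 30 (19 over the list alone; median 0.94, adjusted p = 2.9e-05), p53 targets in 4 of 26 (9; median 0.76, adjusted p = 0.000102) and oxidative phosphorylation genes in 5 of 24 (14; median 0.57, adjusted p = 1.54e-06). With an estimated correlation, YAP/TAZ targets, sterol, lysosomal, p53 and oxidative phosphorylation lists had adjusted p = 0.508. Ribosomal proteins had a median of 0.41 (adjusted p = 3.86e-05, and adjusted p = 0.779 with an estimated correlation), 1 of 38 rising over all genes, and 19 rising and 1 falling over the list alone. Both this list and oxidative phosphorylation were measured against the single HER2 control, the library with the strongest trend with transcript length (Spearman 0.22), and fold changes of this comparison correlated with length at -0.14. The group-means model in edgeR called 0 genes, with 1751 at an unadjusted p under 0.05 and 525 by DESeq2. By the reagent model, the count was 683 (354 higher, 329 lower) and with DESeq2 2393, 0 without control A or control B, and 7057 to 8164 without an siRNA library.

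Averaged over both lines, siRNA lowered 38 of 38 mitosis genes (38 over the list alone; median -2.17, adjusted p = 2.54e-24, and adjusted p = 0.455 with an estimated correlation), and the nuclear lamina gene LMNB1 and the helicase gene PIF1 (-3.45 ± 0.25) were among those named. YAP/TAZ targets fell in 10 of 22 and rose in 1 (13 and 1 over the list alone; median -0.45, adjusted p = 1.42e-05, and adjusted p = 0.398 with an estimated correlation). Interferon genes rose in 20 of 38 and fell in 1 (25 and 2 over the list alone; median 0.77, adjusted p = 3.82e-07, and adjusted p = 0.398 with an estimated correlation and 0.0477 by fry). MAF, CHI3L1, GPNMB, MMP1, BMF and TMOD1 were among the named genes that rose. The group-means model in edgeR called 0 genes, with 4047 at an unadjusted p under 0.05 and 2979 by DESeq2, 2496 without HER2 siRNA 1 and 664 without HER2 siRNA 3. The reagent model called 4754 (2336 higher, 2418 lower), 1448 without control A, 1352 without control B and 9387 to 10049 without an siRNA library.

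**Figure D3:**
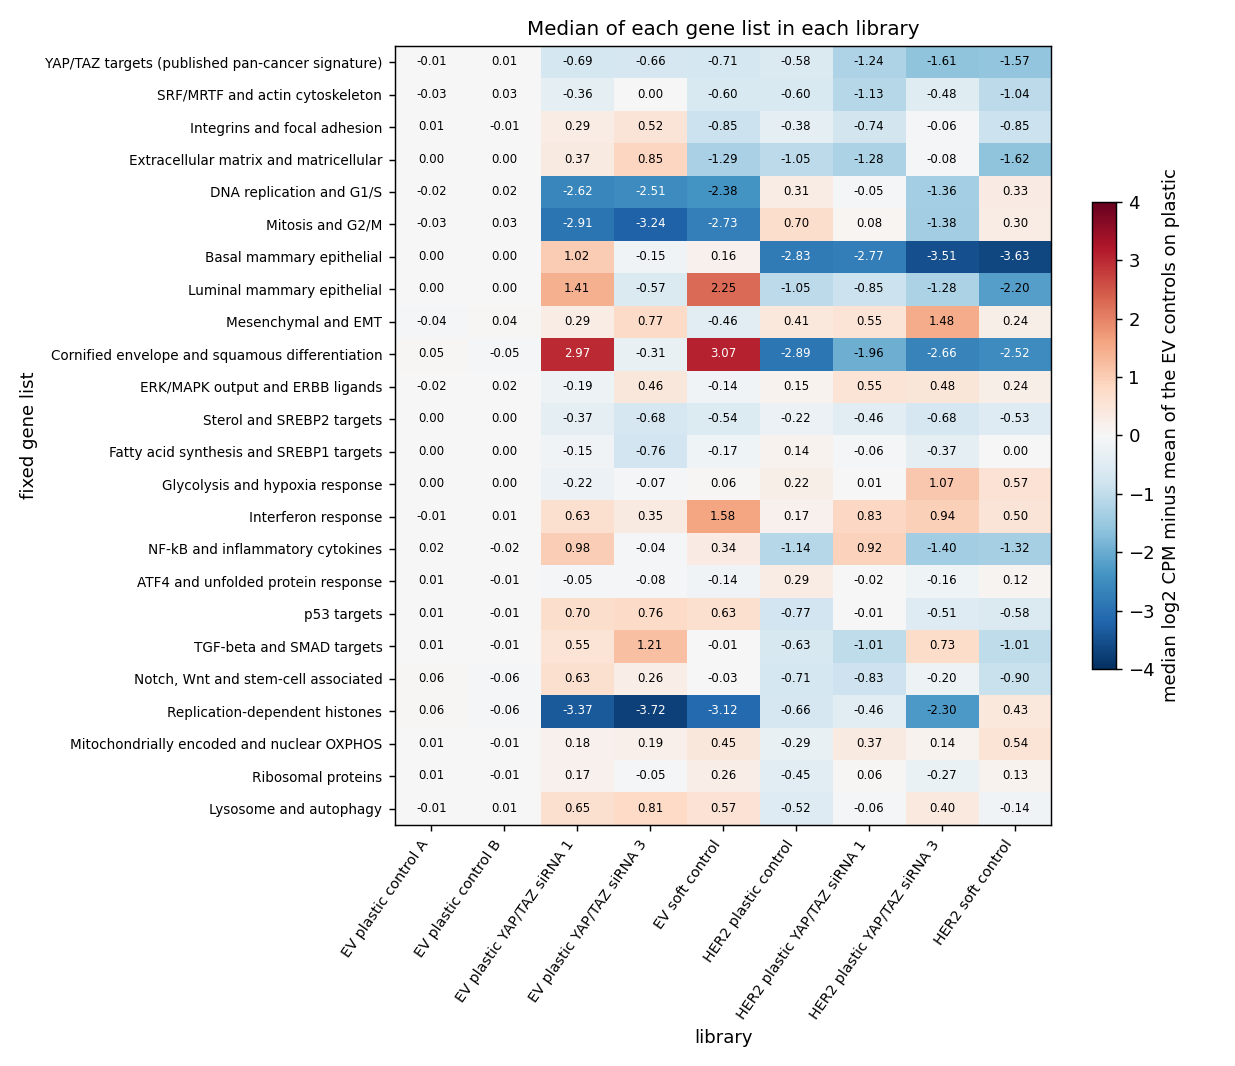
Heatmap of the 24 fixed gene lists (vertical axis) in the 9 libraries (horizontal axis), with color for the median log2 CPM of each list minus the mean of the empty-vector controls on plastic. Mitosis genes stood at -2.91, -3.24 and -2.73 in empty-vector cells with siRNA 1, with siRNA 3 and on the hydrogel, against 0.08, -1.38 and 0.30 in HER2 cells.

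Whether HER2 cells respond otherwise than empty-vector cells was tested as an interaction. For the hydrogel, mitosis genes had an interaction of 2.31, replication genes of 2.45 and histones of 4.0 (adjusted p = 4.99e-15, 2.11e-16 and 8.36e-15). In HER2 cells their hydrogel medians were -0.37, 0.08 and 1.06, and 0 of 18 histones passed there. Interferon genes had an interaction of -1.36 (adjusted p = 7.65e-09). YAP/TAZ targets did not pass, with -0.28 (adjusted p = 0.351). For siRNA, mitosis genes had an interaction of 1.81 (adjusted p = 1.12e-16), and YAP/TAZ targets of 0.18 (adjusted p = 0.298). With an estimated correlation these lists had adjusted p = 0.778 for the hydrogel, or 0.412 for interferon genes, and adjusted p = 0.865 for siRNA. By gene, edgeR called 0 of 16117 in each interaction. For the hydrogel 1901 had an unadjusted p under 0.05 in the group-means model and 4507 in the reagent model, where DESeq2 called 505 and 2481. For siRNA these numbers were 736 and 2415, and 33 and 633 by DESeq2. The smallest adjusted p in the reagent model were 0.0709 and 0.232, and without an siRNA library that model called up to 8511 and 7238.

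The effects of the hydrogel and of siRNA were set side by side to ask how far softness resembles loss of YAP/TAZ. Between lines, where no library is shared, the hydrogel effect in empty-vector cells correlated with the siRNA effect in HER2 cells at r = 0.27 across 16117 genes by fitted fold changes. It was 0.36 by log2 CPM with a prior count of 2, with the same sign in 62.7%. The hydrogel effect in HER2 cells correlated with the siRNA effect in empty-vector cells at r = 0.10 by fitted fold changes and 0.14 by log2 CPM, with the same sign in 54.7%. In this pair, fold changes correlated with transcript length at -0.37 and 0.10 (Spearman), whose part in r was not tested. Of reagent model calls, the first pair shared 168 higher and 123 lower genes, against 36.2 and 32.7 for independent lists. The second pair shared 4 and 14, against 0.7 and 3.3. Both lists of a pair use 1 estimate of spread, which alone can raise the overlap. Genes are not independent replicates, so no p is given. Within a line the control libraries are shared, which alone produces a correlation. By log2 CPM, r in empty-vector cells was 0.66 and the covariance 0.89, against 0.40 ± 0.01 (SD of 100 draws) and 0.19 in simulated unchanged groups. In HER2 cells r was 0.52, below the simulated 0.62 ± 0.007 (SD of 100 draws), with a covariance of 0.55 against 0.39. By reagent, r within empty-vector cells was 0.73 with siRNA 1 (simulated 0.32 ± 0.01) and 0.42 with siRNA 3 (simulated 0.33 ± 0.011). Within HER2 cells it was 0.59 (simulated 0.55 ± 0.008) and 0.32 (simulated 0.54 ± 0.008), each SD over 100 draws. All draws, those of control libraries included, took the spread of the group-means model, which holds the difference between reagents. The simulated values may therefore be too high, and the HER2 values do not settle whether more than the control is shared. THBS1 and CYR61 fell in both lines with either treatment in the reagent model, and CTGF in each but on the hydrogel in HER2 cells.

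**Figure D4:**
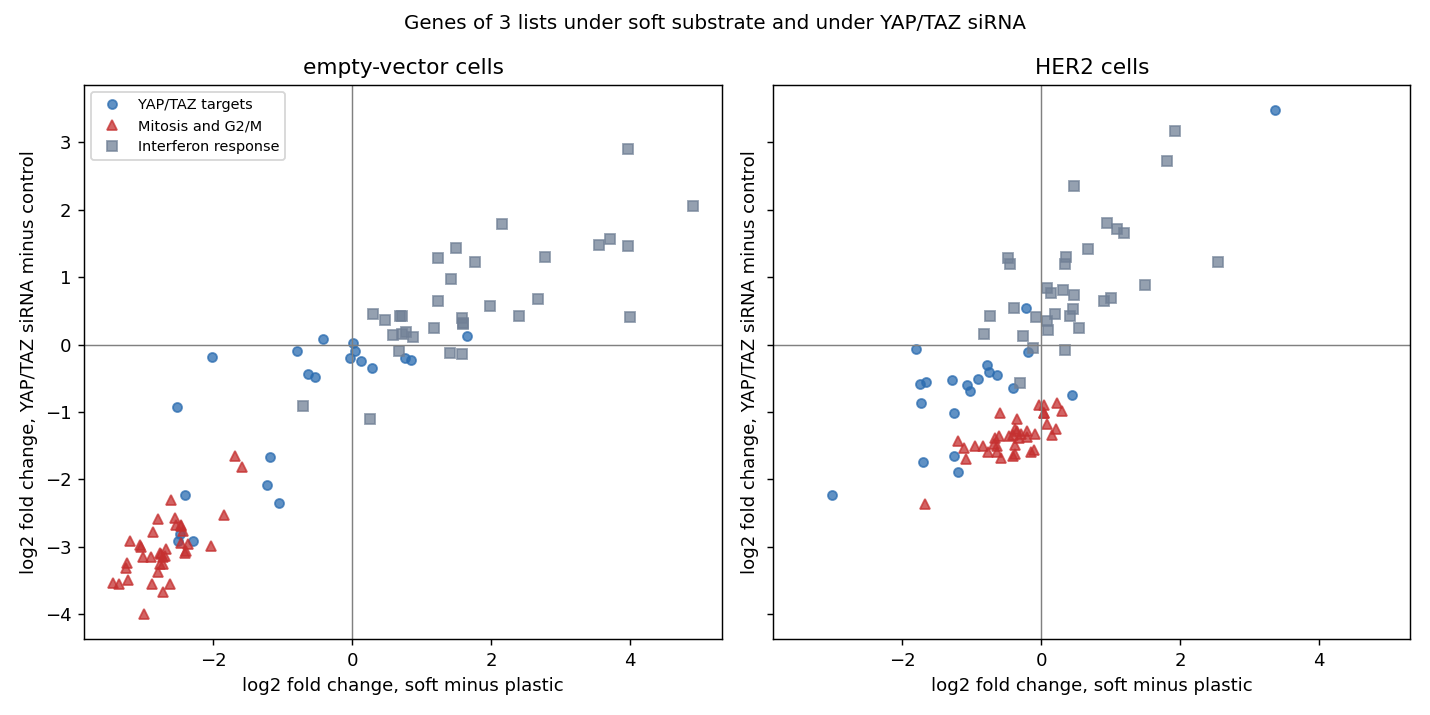
Log2 fold change on the soft hydrogel (horizontal axis) against that under YAP/TAZ siRNA (vertical axis), from the reagent model, for genes of the YAP/TAZ target, mitosis and interferon lists in empty-vector and in HER2 cells; 1 YAP/TAZ target and 5 interferon genes with 3 or fewer counts in a library are not drawn. All 38 mitosis genes fell under both treatments in empty-vector cells, and in HER2 cells their medians were -0.37 on the hydrogel and -1.36 with siRNA.

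The siRNA 3 and siRNA 1 libraries were compared within lines to see how far the reagents differ. TIMP1, an inhibitor of matrix proteases, was higher with siRNA 3 by 4.22 ± 0.33 (adjusted p = 0.00724), IL33 by 7.07 ± 1.06, MMP1, SPP1 and SCG5 by 4.48 or more, and the cystine transporter SLC7A11 by 3.41 ± 0.15. Lower with siRNA 3 were S100A8 (-6.92 ± 0.15, adjusted p = 0.00111), S100A7 (-7.55 ± 0.21), SPRR3 and C7, and also CDH1 (-2.68 ± 0.26) and KRT14 (-3.22 ± 0.25). Of 33 cornified envelope genes 20 were lower (23 adjusted over the list alone; median -3.34, adjusted p = 5.79e-06, and adjusted p = 0.494 with an estimated correlation). Of 32 NF-kB genes 16 were lower and 1 higher (20 and 1 over the list alone; median -2.0, adjusted p = 4.53e-06, and adjusted p = 0.481 with an estimated correlation). Of 24 mesenchymal genes 10 were higher and 1 lower (13 and 1 over the list alone; median 0.78, adjusted p = 2.16e-06, and adjusted p = 0.45 with an estimated correlation and 0.0167 by fry), and of 31 matrix genes 12 and 1 (15 and 1 over the list alone; median 0.83, adjusted p = 7.08e-06, and adjusted p = 0.45 with an estimated correlation). YAP/TAZ targets and interferon genes did not pass, with medians of 0.14 (adjusted p = 0.24) and 0.00 (adjusted p = 0.981). In all, edgeR called 2695 genes (1186 higher, 1509 lower with siRNA 3) and DESeq2 3929. Without control A 712 passed, without control B 706, and up to 9237 without an siRNA library.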

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

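Each result below drew attention because the change of a fixed list on the hydrogel or under siRNA differed between HER2 and empty-vector cells, by an interaction in camera (limma) with a preset correlation. The length test on the principal coding transcript was chosen only after the result with the longest transcript was seen. The other tests on ribosomal proteins were written after that pattern had been seen, and before their own values were. The list tests without single libraries were added after the data were seen. With all 9 libraries no gene passed either interaction in the group-means or the reagent model of edgeR (1901 and 736 at an unadjusted p under 0.05 in the former, 505 and 33 by DESeq2), while reagent models without an siRNA library called up to 8511 and 7238.

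On the hydrogel, the interaction (HER2 minus empty vector, median log2) was 2.31 for 38 mitosis genes (adjusted p = 4.99e-15). It was 2.45 for 36 DNA replication genes (adjusted p = 2.11e-16). For 18 replication-dependent histones it was 4.0 (adjusted p = 8.36e-15). Actin cytoskeleton genes differed by 0.66 (adjusted p = 0.0125). Oxidative phosphorylation genes differed by 0.44 (adjusted p = 0.00936), their median being -0.29 in the HER2 control on plastic, 0.37 and 0.14 with siRNA 1 and siRNA 3 and 0.54 on the hydrogel. Luminal genes differed by -2.26 (adjusted p = 0.000501), with 5 of 25 members at 3 or fewer counts in both HER2 groups. Cornified envelope genes differed by -3.28 (adjusted p = 3.69e-05), with 21 of 33 members so low. Interferon genes differed by -1.36 (adjusted p = 7.65e-09, and 0.412 with an estimated correlation). The other lists of this paragraph had adjusted p = 0.778 with an estimated correlation, and each HER2 support was seen in 1 library.

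Under siRNA, the interaction was 1.81 for mitosis genes (adjusted p = 1.12e-16), whose medians against empty-vector controls were 0.70 in the HER2 control, 0.08 and -1.38 there with siRNA 1 and siRNA 3, and -2.91 and -3.24 in empty-vector cells. It was 1.78 for DNA replication genes (adjusted p = 1.37e-17), with medians of 0.31, of -0.05 and -1.36, and of -2.62 and -2.51. Histones differed by 3.12 (adjusted p = 8.52e-16). Oxidative phosphorylation genes differed by 0.47 (adjusted p = 0.000576). Basal genes differed by -0.59 (adjusted p = 0.00456, and 0.444 without empty-vector siRNA 1). Cornified envelope genes differed by -1.91 (adjusted p = 0.00166, 0.378 in the other direction without empty-vector siRNA 1 and 0.0759 without HER2 siRNA 3), with 19 of 33 members at 3 or fewer counts in both HER2 groups. With an estimated correlation each had adjusted p = 0.865. Across genes, the hydrogel and siRNA interactions correlated with transcript length at -0.24 and -0.29 (Spearman), and matched lists were drawn for ribosomal proteins alone.

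Ribosomal proteins differed by 0.35 on the hydrogel (adjusted p = 0.0103, and 0.899 with an estimated correlation) and by 0.33 under siRNA (adjusted p = 0.000408, 0.0777 without empty-vector siRNA 3 and 0.865 with an estimated correlation), because they stood lower in the HER2 control on plastic (-0.45) than with siRNA 1 (0.06), with siRNA 3 (-0.27) or on the hydrogel (0.13). That control had the fewest counts. After thinning every library to its depth the hydrogel change in HER2 cells was 0.59 against 0.60 before. Thinning keeps the expected proportions of abundant genes, so this value could hardly move, and it does not decide whether a fault of that shallow library played a part. Transcript length may account for part, since 10000 random lists of like principal length and abundance had a median of 0.29, with the upper limit of their 95% range at 0.55. The list's 0.60 lay above that by a narrow margin and above the 0.30 found with the longest transcript. The random lists held separately drawn genes, so their range leaves out correlation between members of a list. Whether length is the whole cause is therefore not settled. A state of the HER2 cells on plastic stays open and was not tested, since that group holds 1 library.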

How the results depend on the processing

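Fits with libraries of 1 siRNA only, list tests with 1 siRNA or without single libraries, and the alternatives run within the reagent model, were chosen after seeing the data, and the others were set earlier. Single-gene values were followed only for the 192 pairs of gene and comparison that met the rule for named genes. No such value that passed, as reported or under an alternative, had the other sign in the other fit. The rule asked for large fold changes and separated groups, so these signs could hardly turn. Of list tests 11 turned direction, all of them siRNA results fitted with 1 reagent or without 1 siRNA library. With 3 residual degrees of freedom the counts of the group-means model moved widely, though signs of the genes that met the rule held. Of their values 2225 kept their side of the threshold, 899 passed it only under an alternative and 79 only as reported. Of list tests these numbers were 2218, 124 and 239. Where a fit kept 1 siRNA, or only the compared groups for HER2 on plastic and for the hydrogel, the spread rested on the A and B pair alone, which by construction left out the difference between reagents and gave large counts. The additive model has 1 effect shared by both lines, so its 16 and 1097 are not counts for a line. Its HER2 effect is shared by all supports and siRNAs, so its 4520 is not a count for plastic. Unless stated below, the cause of the other shifts was not tested. Depth limits what can be called low: in the HER2 control, the shallowest library, 3 counts correspond to 0.131 CPM. Genes named by the rule were given as bounds at 0 counts and as ratios with a counting interval at 1 to 3 counts. This was not done for averages over both lines or between reagents. Hydrogel against plastic in HER2 cells alone could not be fitted with only its groups, which leaves 0 residual degrees of freedom.

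HER2 on plastic was 166 as reported, 400 with no filter, 4520 in the additive model, 2306 with DESeq2, 9666 with only the compared groups, 9523 with siRNA 1 only, 9530 with siRNA 3 only and 3598 in the reagent model. Leaving out 1 library gave 0 to 1011, with 0 without control A or B.

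For the hydrogel in empty-vector cells, where 0 genes passed as reported, the counts were 3 with upper quartile scaling, 9 with no filter, 3 with a robust fit, 16 in the additive model, 1843 with DESeq2, 10273 with only the compared groups, 10270 with siRNA 1 only, 10249 with siRNA 3 only, 3254 in the reagent model and 0 to 638 leaving out 1 library. In HER2 cells 0 became 16 in the additive model, 303 with DESeq2, 7914 with siRNA 1 only, 7870 with siRNA 3 only and 30 in the reagent model. It stayed 0 without each library. In both lines 0 became 15 with no filter, 16 in the additive model, 1291 with DESeq2, 9279 with only the compared groups, 9161 with siRNA 1 only, 9140 with siRNA 3 only and 2241 in the reagent model. It stayed 0 without each library.

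For siRNA in empty-vector cells 0 became 1 with RLE scaling, 1 with upper quartile scaling, 475 with no filter, 1097 in the additive model, 2274 with DESeq2, 1615 with only the compared groups, 9954 with siRNA 1 only, 10364 with siRNA 3 only, 4139 in the reagent model and 0 to 1431 leaving out 1 library. In HER2 cells 0 became 1097 in the additive model, 525 with DESeq2, 7426 with siRNA 1 only, 9022 with siRNA 3 only and 683 in the reagent model. In both lines 0 became 661 with no filter, 1097 in the additive model, 2979 with DESeq2, 9331 with siRNA 1 only, 10652 with siRNA 3 only, 4754 in the reagent model and 0 to 2496 leaving out 1 library. With only the compared groups, siRNA in HER2 cells and in both lines stayed at 0.

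The hydrogel interaction went from 0 to 505 with DESeq2, 8548 with only the compared groups, 8442 with siRNA 1 only and 8441 with siRNA 3 only. The siRNA interaction went from 0 to 33 with DESeq2, 7199 with siRNA 1 only and 5052 with siRNA 3 only. The 2695 genes between siRNA 3 and siRNA 1 became 9975 with a separate reagent term in each line and 706 to 9237 leaving out 1 library. With separate terms the spread rested on the A and B pair alone, so 9975 leaves out how the reagent difference varied between lines.

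Within the reagent model, leaving out 1 library gave 502 to 9606 for HER2 on plastic, 308 to 10299 for the hydrogel in empty-vector cells, 0 to 7910 in HER2 cells and 262 to 9229 in both. It gave 525 to 10600 for siRNA in empty-vector cells, 0 to 8164 in HER2 cells and 1352 to 10049 in both, and 0 to 8511 and 0 to 7238 for the hydrogel and siRNA interactions. The low ends came without control A or B, and the high ends without an siRNA library, where the spread again rests on the A and B pair. DESeq2 with the reagent term gave 1874 for the hydrogel in HER2 cells, 3583 in both lines, 2393 for siRNA in HER2 cells, and 2481 and 633 for the interactions. With no filter the hydrogel in HER2 cells gave 251.

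The share of HER2-response genes with the same sign on the hydrogel was 97.1% with RLE scaling, 95.5% with a filter at 50 counts and 86.5 to 98.4% leaving out 1 library, each over the genes called there, and 94.8 to 100% under siRNA. The correlation of siRNA in empty-vector cells with the hydrogel in HER2 cells, 0.10, was 0.14 by log2 CPM and 0.08 to 0.11 leaving out 1 library. That of siRNA in HER2 cells with the hydrogel in empty-vector cells, 0.27, was 0.37 with a filter at 50 counts, 0.36 by log2 CPM, 0.21 with siRNA 3 only and 0.20 to 0.28 leaving out 1 library.

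Of the 24 lists, those past the threshold numbered 11 for HER2 on plastic, 15, 10 and 15 for the hydrogel (empty vector, HER2, both), 14, 10 and 13 for siRNA, and 9 and 7 for the interactions. With an estimated correlation each count was 0. With fry they were 0, then 1, 0 and 1, then 0, 0 and 1, then 0 and 0, and in the reagent model 12, then 10, 3 and 11, then 4, 0 and 10, then 0 and 0. The hydrogel interaction had 14 in the reagent model. HER2 on plastic had 17 with siRNA 1 only and 18 with siRNA 3 only, siRNA in HER2 cells 18 with siRNA 3 only, and the siRNA interaction 6 to 12 leaving out 1 library.

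As adjusted p, cornified genes turned direction with siRNA 3 only at 0.354 for siRNA in empty-vector cells (3.57e-16 to 0.563 leaving out 1 library), at 0.701 in both lines (7.48e-10 to 0.944) and at 0.725 for the interaction (1.64e-16 to 0.378). Histones in HER2 cells turned with siRNA 1 only at 0.205 (6.1e-11 to 0.287). With siRNA 3 only, actin cytoskeleton genes in HER2 cells turned and passed at 0.0345, and NF-kB genes in the siRNA interaction at 0.0158 (0.00605 to 0.506).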

Other observations

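The tests of this part were written after the patterns they address, the correlations between libraries and the counts of calls had been seen, and before their own values were. The genes of the next 2 paragraphs were chosen only after their values were seen.

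Some single genes differed widely between libraries, while the fixed list of fatty acid synthesis did not pass for HER2 on plastic (median 0.14, adjusted p = 0.0952). FABP4, a fatty acid carrier, was 7.35 CPM in empty-vector controls and 470 CPM in the HER2 control (6.0 ± 0.51 in the reagent model, edgeR adjusted p = 0.00582), then 9489 CPM with siRNA 1, 266.3 CPM with siRNA 3 and 6539 CPM on the hydrogel. LPL, the lipoprotein lipase, stood at 32.9 CPM in the HER2 control against 0.307 CPM (6.73 ± 0.27, adjusted p = 0.00223), and the fatty acid receptor CD36 at 9.19 against 0.229 CPM (5.33 ± 0.96, adjusted p = 0.022). CIDEC, a lipid droplet protein, was 5.08 against 0.0679 CPM (6.18 ± 0.50). Between reagents, siRNA 3 stood below siRNA 1 by -5.94 ± 0.50 for FABP4, -4.22 ± 0.27 for LPL and -5.37 ± 0.83 for CD36. The secreted HP, with 0 counts in empty-vector controls, was at least 350-fold higher in the HER2 control, and the epithelial factor ELF3 and the claudin CLDN4, with 0 counts in the HER2 control, were at least 191-fold and 149-fold lower.

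Single members of the ATF4 and unfolded protein response list changed, though the list passed neither for HER2 on plastic (median 0.29, adjusted p = 0.265) nor for siRNA in both lines (-0.15, adjusted p = 0.706). PHGDH, the entry enzyme of serine synthesis, rose by 1.31 ± 0.24 in HER2 cells (adjusted p = 0.0234) and fell by 1.29 ± 0.21 with siRNA in empty-vector cells, while its change in HER2 cells, -1.12 ± 0.24, did not pass (adjusted p = 0.0676). PSAT1 rose by 0.85 ± 0.16 and changed by -1.61 ± 0.13 and -1.31 ± 0.15 with siRNA in empty-vector and HER2 cells. ASNS, the asparagine synthetase, rose by 0.83 ± 0.15 and changed by -0.99 ± 0.13 and -1.58 ± 0.15. ERBB3, the partner receptor of HER2, was 0.656 CPM in the HER2 control (-4.53 ± 0.51 against empty vector, adjusted p = 0.00942) and rose by 3.01 ± 0.32 on the hydrogel in empty-vector cells.

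Markers of other cell types were low as lists. The median of 10 fibroblast markers was highest in empty-vector cells with siRNA 1, at 2.03 CPM, as was that of 10 leukocyte markers, at 2.46 CPM. On the hydrogel these medians in empty-vector cells were 0.585 and 1.15 CPM. In controls A and B they were 0.24 and 0.218 CPM for fibroblast and 0.12 and 0.152 CPM for leukocyte markers. Endothelial and neuronal medians stayed at or below 0.469 and 0.284 CPM. Single members were abundant, with COL6A3 at 307 CPM and LAPTM5 at 110 CPM in HER2 cells with siRNA 3, TUBB3 at 295 CPM in empty-vector cells with siRNA 3 and PECAM1 at 36.4 CPM in HER2 cells with siRNA 1.

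The near absence of CDH1, KRT14 and TP63 in all 4 HER2 libraries could come from another cell line or from other cells. MCF10A lacks the CDKN2A and CDKN2B locus, and the highest level of either gene in the HER2 libraries was 0 CPM, which argues against a line that expresses them, while a line that lacks or silences them stays open. Fibroblast replacement was argued against by the fibroblast markers, whose median was at most 0.401 CPM in HER2 libraries. A change of state under the receptor, or a subclone picked during selection, stays open and was not tested.

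The difference between siRNA 3 and siRNA 1 could reflect low complexity of the siRNA 3 libraries, which had only 579 and 434 genes at 1 to 3 counts (the HER2 hydrogel library had 294, the fewest), or weaker knockdown by siRNA 3. Against low complexity as the cause in abundant genes, the difference correlated between lines, which share no library, at 0.67 across the 4030 most abundant genes. Across all 16117 genes it was 0.42, and for rare genes low complexity stays open. The correlation speaks only against loss that was independent in the siRNA 3 libraries. A technical difference common to both could give it too. Weaker knockdown would turn the difference against the siRNA 1 effect, but the correlations across lines were 0.02 and -0.21, so it cannot be told apart from other causes, and WWTR1 was 0.68 ± 0.11 higher with siRNA 3. Genes moved by 1 reagent apart from YAP and TAZ stay open, as no reagent was tested without its targets.

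For siRNA in both lines the 7 plastic libraries were also divided otherwise, with line as a term. The real division called 917 genes, and 2 of 34 divisions gave as many, so chance is not excluded by this count. The other was the division that put HER2 siRNA 1 with the control libraries, which called 2609 genes and points to a structure of the samples. In HER2 cells with siRNA 1 the mitosis list stood at 0.08, near the empty-vector controls, and with siRNA 3 at -1.38, although YAP1 was left at 8.5% and 16.5%. With reagent as a term too, added after that count was seen, the real division called 4161 genes and was the only 1 of 34 to reach that, with 3770 for HER2 siRNA 1 among controls, but this term takes the real reagent labels and so favors the real division.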
